A study of Triticum aestivum with 18 samples.

How the data were processed

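The 18 dual-colour Agilent arrays held embryos of wheat grown in adjoining greenhouse rooms kept at 13 °C and 25 °C after anthesis, per the labels' protocols. Total RNA was extracted with Trizol and labelled with Cy3 or Cy5, per the labels' protocols. The deposited scanner files hold 39243 spots per array with mean signals and background medians in linear intensity, flags for each spot, and log10 ratios of Cy5 over Cy3 computed by Agilent Feature Extraction, per the file headers. The submitters' processing notes name Feature Extraction 9.1, while the file headers give version 9.1.3.1 for the 4 arrays of replicate 1 of the mature embryos and 9.5.3.1 for the other 14. The authors' deposited series table equals the scanner files' log10 ratios at every spot (tolerance 1e-05), with the sign turned on the 2 dye-swapped arrays, so its scale and direction are settled. The median of each of its columns is 0.

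From the files, mean signals were corrected with normexp (offset 50) against the background medians, and each array was normalized by loess with control spots at weight 0 (limma 3.58.1 in R 4.3.3). The 1417 control spots and spots flagged as outliers were left out, between 3 and 148 spots per array, and saturated spots were kept. In 1 array, the 25 °C embryos of 25 days, 5 spots had a local background over 3 times the array's median. With them kept, the SD of the background in the normexp fit of that array was 519 in Cy3 and 563.6 in Cy5, and 0.4 and 1.2 without them. Keeping them moved 69.2% of the array's tested probes by over 0.1 on the log2 scale, and the SD of its log2 ratios was 0.55 with them and 0.85 without. After seeing the data these spots were left out, and the version with them kept is an alternative. All mature ratios were turned to 13 °C over 25 °C. The dye-swapped pair of replicate 1 is the same 2 RNAs and was averaged, so it counts as 1 replicate. Replicates 2 and 3 are called biological repeats in the labels and have 1 dye orientation, so a dye effect does not cancel in them. In the swap pairs the dye effect had an SD of 0.107 (N61) and 0.110 (SK) on the log2 scale, and the 2 arrays of a pair correlated at 0.913 and 0.922. In the fit with a dye term, the dye effect passed the threshold at 12634 of 29682 probes.

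A mature probe was tested if it was well above background in the channel of either temperature on at least 3 of the 8 arrays (29708 probes), and a time course probe if its sample or reference channel was so on at least 3 of the 10 arrays (28170 probes). Linear models were fitted to log2 ratios with limma (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The mature fit held a mean per cultivar over 6 replicates, and its contrasts gave N61, SK, their average and their difference. The time course fit held an intercept and a slope on days per temperature over 10 arrays. The temperature difference of the time course was fitted with relative age and its square. Probes were named by a rule fixed before the data were examined: per fit, the 2 highest and 2 lowest log2 values among probes past the threshold, well above background in both channels on the arrays of the fit (for mature fits on all 8), and, for mature embryos, of the same sign in every replicate. The rule asked for up to 10 each way with a gene annotation, which does not apply because the files do not pair the probes with gene names. Of the 6 probes that carry a gene name only RD29B was tested, and it did not pass the threshold. In the reference gene table (IWGSC CS RefSeq v2.1) 0 probe names were matched. The designs, the groups, the lists and all alternatives not said to be added were also fixed before the data were examined.

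The arrays lie on 6 slides and were scanned in 3 sessions. Replicate 1 of both cultivars shares slide 1 and scan 1. Replicates 2 and 3 were scanned in session 3, on slide 5 for N61 and slide 6 for SK, and the time course in session 2 on slides 2, 3 and 4. Replicate numbers pair the samples by their data: the deviations of same-numbered replicates of the 2 cultivars from their means correlated at 0.65, 0.42 and 0.36 over probes. The labels do not say what the numbers share, and the pairing follows the scan sessions in part. Spike-in controls gave slopes of observed on expected log ratios between 0.80 and 0.95, per the file headers.

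The fits were tested on simulated data with each probe's real SD, 100 probes changed 2-fold and 100 changed 4-fold. For N61 mature embryos (29708 probes) 71% of the 2-fold and 97% of the 4-fold changes were recovered, for SK 73% and 95%, and for both cultivars 79% and 97%. For the cultivar difference 43% and 80% were recovered. For a slope of 2-fold and 4-fold per 10 days the shares were 83% and 99% at 13 °C and 40% and 83% at 25 °C (28170 probes), and for the temperature difference of the time course 39% and 89%. Between 3 and 9 unchanged probes were called in each. The simulated noise was independent between arrays and probes, without the deviations that real replicates or slides share. The shares recovered and the false calls therefore do not give error rates under such shared deviations.

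Alternatives were Feature Extraction's ratios, median centring, no background correction, Aquantile scaling, no filter or a strict filter, the series table, a dye term, the swapped arrays left out, a trended and robust spread, each cultivar alone, slide, scan session and replicate blocks, a 2-fold threshold, other time scales, and each replicate or time point left out. Gene lists were matched by name and none had 5 tested members. Figures were drawn with matplotlib 3.10.9.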

Results

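Gene expression was measured in embryos of bread wheat seeds that developed at 13 °C or at 25 °C after flowering. The cultivars were Norin 61 (N61) and Shiroganekomugi (SK). Each of the 18 arrays carried 2 labelled RNAs, 1 in Cy3 and 1 in Cy5. On 8 arrays mature embryos of the 2 temperatures were set against each other. N61 embryos were taken at 76 days after anthesis at 13 °C and at 39 days at 25 °C, and SK embryos at 80 and 43 days. Each cultivar had 3 biological replicates on 4 arrays, because replicate 1 was hybridised again with the dyes exchanged. The other 10 arrays formed a time course of N61, with 1 array for each of 5 ages per temperature, all against mature 13 °C embryos of 76 days. Between 64.6% and 73.9% of the 37826 probes were well above background in Cy3, and between 63.6% and 78.9% in Cy5. The number of arrays limits the precision of every value below, and the time points have no replicates. The temperatures were kept in adjoining greenhouse rooms, so temperature may go together with other differences between the rooms, in both cultivars. The p-values below do not cover such differences.

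Mature N61 embryos differed between the temperatures at 2935 of 29708 tested probes (limma, adjusted p under 0.05). Of these, 1398 were higher in embryos that had developed at 13 °C and 1537 were lower, and 435 differed at least 2-fold. The files do not pair these probes with gene names, so probes are given by the names the files hold. The probe of wheat0130Contig12202 was 18.9-fold higher at 13 °C (log2 4.24 ± 0.14 SE, n = 3, adjusted p = 0.00028), with replicate values of 4.64, 4.08 and 4.01. It was higher in 3 of 3 replicates. Each probe named for a single cultivar was higher or lower in 3 of 3, because the naming rule asked for it. The probe of wheat0130Contig787 was 10.1-fold higher (log2 3.33 ± 0.21, adjusted p = 0.0032). In the other direction, MUGEST2003_23lib_Contig7628_m_1111 had a log2 value of -2.60 ± 0.35 (adjusted p = 0.010) and MUGEST2003_23lib_Contig11395_811 had -2.32 ± 0.28 (adjusted p = 0.0082), and both lost the call without N61 replicate 3, the second also without replicate 1. Of the 2935 probes, 2805 were well above background in both channels on all 4 N61 arrays. On none of the 4 arrays were 19 of them well above background at 13 °C, or 4 of them at 25 °C, while the other temperature was so on all 4. The count was 404, 373 and 37 without N61 replicate 1, 2 and 3, and 4511 and 1519 without SK replicate 1 and 2, which share the estimate of the spread. It was 1541 (237 higher, 1304 lower) with median centring, 1336 with a trended and robust spread, 1422 with the slide as a random block, 8510 with the scan session as a block, 8021 with the replicate number as a block and 4427 in the later session alone, the last 2 chosen after seeing the data.

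Mature SK embryos differed between the temperatures at 3522 probes, 1473 higher and 2049 lower at 13 °C, and 495 of them by at least 2-fold. The probe of wheat0130Contig12202 was 19.2-fold higher at 13 °C (log2 4.26 ± 0.14 SE, n = 3, adjusted p = 0.00027). MUGEST2003_23lib_Contig17196_804 was 11.4-fold higher (log2 3.51 ± 0.18, adjusted p = 0.0014). The probe of wheat0130Contig14075 had a log2 value of -3.90 ± 0.50 (adjusted p = 0.0086), and that of wheat0130Contig6297 had -2.93 ± 0.28 (adjusted p = 0.0048). The call of wheat0130Contig14075 was lost without SK replicate 2 or 3. When SK was fitted alone on its 3 replicates only 7 probes passed, and MUGEST2003_23lib_Contig17196_804 and wheat0130Contig6297 were not among them (adjusted p = 0.053 and 0.058). The count was 602 and 451 without SK replicate 2 and 3, and 1914 and 1606 without N61 replicate 2 and 3. It was 1893 with a trended and robust spread, 1466 with the slide as a random block, 9367 with the scan session as a block, 8709 with the replicate number as a block and 6173 in the later session alone. Median centring gave 477 higher and 3248 lower probes.

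Averaged over both cultivars, 8178 of 29708 probes (27.53%) differed between the temperatures, 3902 higher and 4276 lower at 13 °C. Most of these differences were small, with a median size of 0.443 on the log2 scale, and 478 reached 2-fold. The probes of wheat0130Contig12202 (log2 4.25 ± 0.10 SE, n = 6) and wheat0130Contig787 (log2 3.40 ± 0.15) were higher at 13 °C in 6 of 6 replicates, with adjusted p values of 2.6e-05 and 0.00026. The probes of wheat0130Contig6297 (-2.62 ± 0.20, adjusted p = 0.00077) and MUGEST2003_23lib_Contig7628_m_1111 (-2.52 ± 0.24, adjusted p = 0.0013) were lower in 6 of 6 replicates. The naming rule asked for the same sign in every replicate, so that agreement is no separate support. All 4 probes kept their calls in each of the 22 alternative settings and left-out replicates tried. Not all of these could change a call. Aquantile scaling and keeping spots of high background moved no mature ratio. The series table repeated Feature Extraction's ratios, and the 2-fold threshold reused the same p-values. The count fell to 4713 without N61 replicate 3 and to 3699 with the slide as a random block. It was 13621 with the scan session as a block and 13203 with the replicate number as a block. The fit took the 6 replicates as independent, but deviations of same-numbered replicates correlated between the cultivars (0.65, 0.42 and 0.36). The SEs and adjusted p values over both cultivars may thus be too small, and the count too high. The session and replicate blocks take such shared variation out of the spread, so they do not settle this. Median centring gave 1560 higher and 5911 lower probes.

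**Figure D1:**
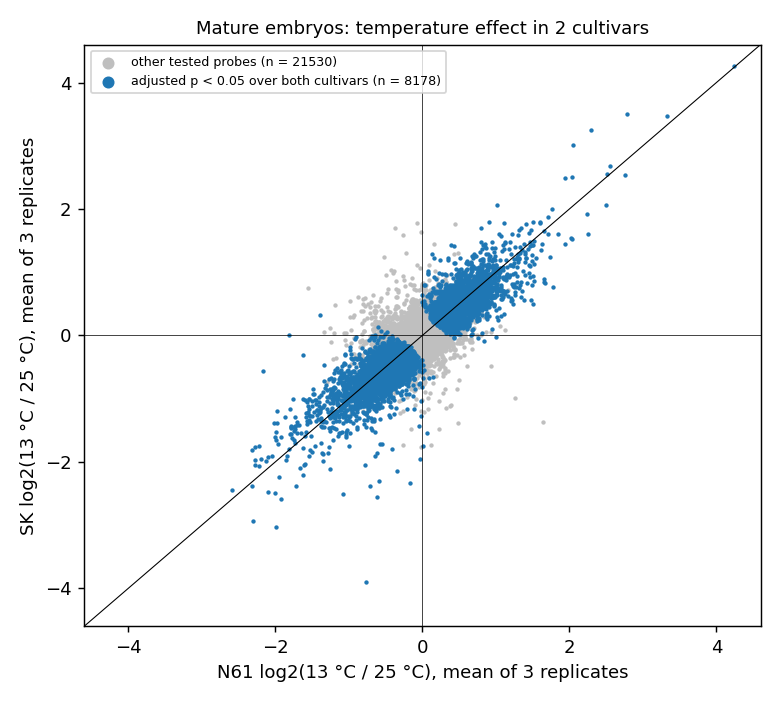
Mean log2(13 °C / 25 °C) of mature embryos in N61 (x axis) and SK (y axis), each the mean of 3 replicates, with a point per tested probe and the 8178 probes called over both cultivars in blue. The points lie along the diagonal line of equal effects (Pearson correlation over probes 0.834).

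The difference between temperatures had the same direction in both cultivars at nearly every called probe. Of the probes higher at 13 °C, 912 were called in both cultivars, against 69.3 for independent lists of these sizes, and of those lower at 13 °C, 1155 against 106. No probe was called in opposite directions. Of the 2935 N61 calls, 2907 had the same sign in SK, and of the 3522 SK calls, 3482 had the same sign in N61. The lists of both cultivars came from 1 fit with 1 spread per probe, so the values for independent lists are no chance level. Replicates of the 2 cultivars shared scan sessions, and replicates 2 and 3 of both had 1 dye orientation. These overlaps and shared signs are thus not free of a shared batch, greenhouse room or dye effect. In the test of the difference itself (limma, N61 minus SK), 0 probes passed the threshold and 829 had an unadjusted p under 0.05, where 1485 would be expected by chance. This test left the replicates unpaired. Since deviations of same-numbered replicates correlated (0.65, 0.42 and 0.36), its spread may be too large and the 829 too few. With the replicate number as a block 0 probes passed and 2142 had an unadjusted p under 0.05, and within the later session the values were 0 and 1609. The median SE of the difference was 0.17 on the log2 scale. In simulated data 43% of 2-fold differences between the cultivars were recovered, so the lack of calls does not show equal responses. The probe of wheat0130Contig14075, at -3.96, -4.10 and -3.63 in SK and 0.95, -2.09 and -1.16 in N61, differed by 3.13 and did not pass (adjusted p = 1).

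**Figure D2:**
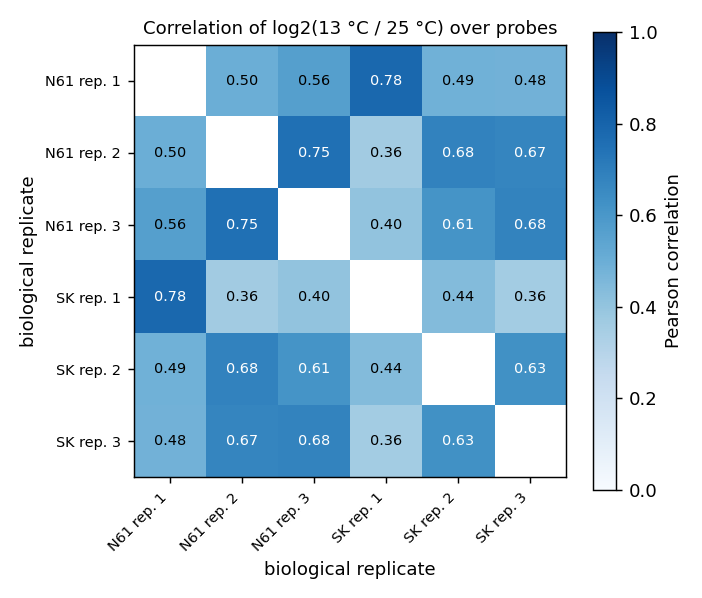
Pearson correlations over probes of log2(13 °C / 25 °C) between the 6 biological replicates of mature embryos (both axes). Replicate 1 of N61 correlated at 0.78 with replicate 1 of SK and at 0.50 and 0.56 with replicates 2 and 3 of N61.

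The time course asked how expression in N61 embryos changed with age at each temperature. Late arrays lay nearer to the mature 13 °C embryo than early ones at both temperatures, and did so at fewer days at 25 °C, with 1 step away from it at each temperature. At 13 °C, 33.6% of 28170 probes differed at least 2-fold from the mature embryo at 25 days after anthesis, 28.9% at 34 days, 18.7% at 43 days, 24.4% at 53 days and 0.6% at 62 days. At 25 °C the shares were 33.3% at 15 days, 20.9% at 20 days, 19.8% at 25 days, 3.4% at 29 days and 6.0% at 34 days. Distances between arrays were taken as the SD over probes of the log2 difference, from which the shared reference cancels. The 25 °C array nearest to the 13 °C arrays of 25, 34, 43, 53 and 62 days was that of 15, 15, 20, 25 and 29 days, at distances of 0.53, 0.42, 0.54, 0.46 and 0.40. Of these 5 pairs the first shares a slide. Arrays of equal days lay further apart, at 1.06 for 25 days and 1.26 for 34 days. These distances have no replicate check.

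**Figure D3:**
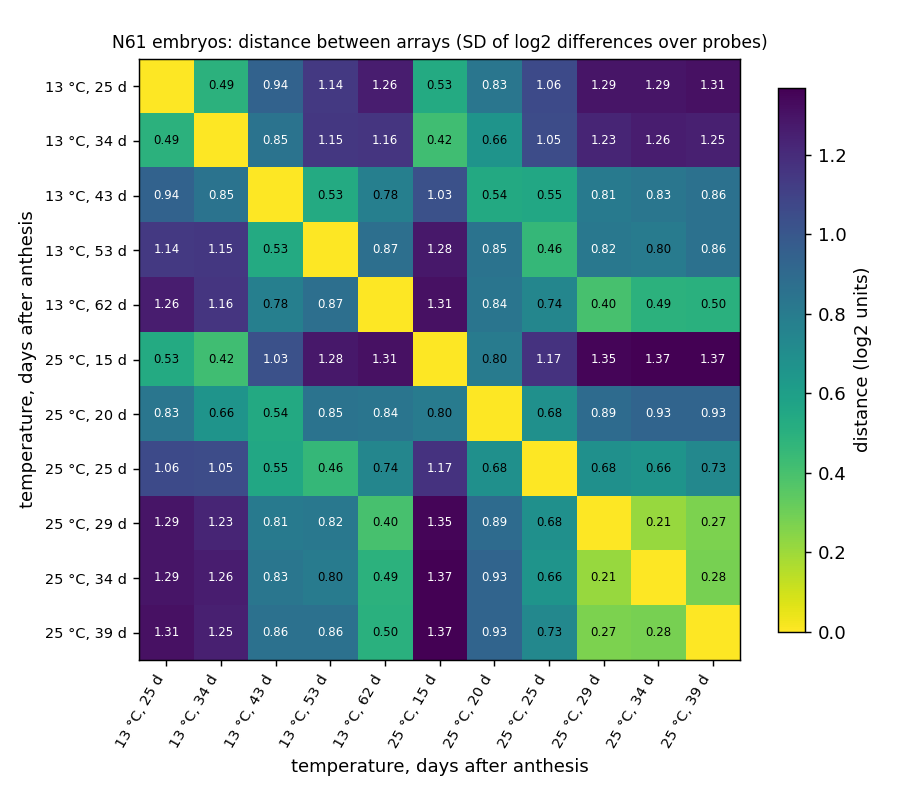
Distance between arrays of N61 embryos (SD over probes of the log2 difference) by temperature and days after anthesis on both axes, with the first mature 25 °C array at 39 days. The 25 °C arrays of 29, 34 and 39 days lie within 0.28 of each other, and the 13 °C array of 62 days lies 0.40 to 0.50 from them.

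The linear trend with age at 13 °C passed the threshold at 4241 of 28170 probes, of which 1692 rose and 2549 fell. The probes of wheat0130Contig2118 and wheat0130Contig8708 rose by 1.92 on the log2 scale per 10 days (SE 0.45 and 0.40, adjusted p = 0.031 and 0.025). The probe of wheat0130Contig3565 fell by 2.23 per 10 days (SE 0.54, adjusted p = 0.033) and that of MUGEST2003_23lib_Contig1047_223 fell by 2.22 (SE 0.47, adjusted p = 0.026). The drop was not even in time: relative to the mature embryo, wheat0130Contig3565 stood at log2 6.59 and 7.27 at 25 and 34 days, 1.12 at 43 days and -0.93 at 53 days. The limma p-values measure scatter around a straight line per temperature, with the spread pooled over the 10 single arrays. The count was 18 without the array of 25 days, 381 without that of 34 days and 0 without that of 62 days (limma, 8246 probes with an unadjusted p under 0.05). All 4 named probes lost their calls without the array of 25, 34 or 62 days, and wheat0130Contig2118 and wheat0130Contig3565 also without that of 53 days. Median centring gave 1151 rising and 3525 falling probes.

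At 25 °C the trend passed at 6850 probes, of which 3218 rose and 3632 fell. The probe of MUGEST2003_23lib_Contig15894_103 rose by 4.37 per 10 days on the log2 scale (SE 0.44, adjusted p = 0.0088) and that of wheat0130Contig2118 by 4.13 (SE 0.89, adjusted p = 0.016). The probe of wheat0130Contig2783 fell by 4.81 per 10 days (SE 0.79, adjusted p = 0.0088) and that of whfl_allContig1333 fell by 4.78 (SE 0.81, adjusted p = 0.0090). Of the probes that rose at 13 °C, 1270 also rose at 25 °C, against 193.3 for independent lists. Of those that fell at 13 °C, 1925 also fell at 25 °C, against 328.6. Both lists came from 1 fit with 1 spread per probe, so the values for independent lists are no chance level. The first array at each temperature lay on slide 2 and the later ones on slides 3 and 4. A slide effect could therefore give slopes of the same sign at both temperatures. Among the 3197 probes called at both temperatures 2 had opposite signs. For the rest the median ratio of the slope at 25 °C to that at 13 °C was 2.05. The ratio of days at maturity was 1.95. The arrays span 15 to 34 days at 25 °C and 25 to 62 days at 13 °C. Slopes at 25 °C thus had larger SEs (0.89 against 0.45 for wheat0130Contig2118) and had to be steeper to pass. This selection can raise the ratio of slopes, so the ratio is no test of faster development. In the test of the slope difference (limma) 0 probes passed per day of age, with 4457 at an unadjusted p under 0.05, and 0 passed on the scale of relative age, with 1046, where 1408 would be expected by chance. The count at 25 °C was 0 without the array of 15 days (6246 probes with an unadjusted p under 0.05), 4564 without 20 days, 2566 without 29 days and 3437 without 34 days, and the 4 named probes lost their calls without the array of 15 days.

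Between the temperatures, at the same relative age, few probes passed a test in the time course. Relative age was the days after anthesis divided by 76 at 13 °C and by 39 at 25 °C. It may not align the stages. At relative age 0.7 at 13 °C, 24.4% of probes differed at least 2-fold from the mature 13 °C embryo, and at 0.74 at 25 °C 3.4% did. In simulated data 39% of 2-fold temperature differences were recovered. Few calls may thus come from poor alignment or low power. With it, 4 of 28170 probes passed (limma, 3 higher and 1 lower at 13 °C), and 1908 had an unadjusted p under 0.05. The probe of wheat0130Contig4445 was higher at 13 °C by log2 2.26 (SE 0.22, adjusted p = 0.035) and that of wheat0130Contig3270 by 1.65 (SE 0.12, adjusted p = 0.0077). The probe of wheat0130Contig14407 had -1.35 (SE 0.15, adjusted p = 0.049). All 3 had a difference of the same sign in mature embryos, of 2.51, 1.49 and -1.63 in N61. Of 21 alternative settings and left-out time points, wheat0130Contig4445 lost its call in 13, wheat0130Contig3270 in 9 and wheat0130Contig14407 in 17. Over these settings the log2 values ranged from 1.74 to 3.19, from 1.25 to 2.31 and from -1.70 to -0.10, the last with days in place of relative age. With the slide as a random block they were 1.83, 1.49 and -1.55, and with the serial number as a block 2.41, 1.59 and -1.15. The count was 7281 with days in place of relative age (4134 higher, 3147 lower), 0 with the serial number of the sample as a block (2264 at an unadjusted p under 0.05), 0 with the slide as a random block (2773) and 51 with the slide as a fixed block, a setting chosen after seeing the data. It was 1 with the scanner software's own ratios, 0 with spots of high local background kept (2180), and 1, 0, 0, 0 and 15 without the 13 °C arrays of 25, 34, 43, 53 and 62 days. Without the 25 °C arrays of 20, 25, 29 and 34 days it was 1, 1, 0 and 0. With a time point left out, between 1294 and 2675 probes had an unadjusted p under 0.05. Only the slide with the 13 °C array of 25 days and the 25 °C array of 15 days held both temperatures, and the difference of that pair correlated with the difference fitted on the other 8 arrays at a Spearman value of 0.10 over probes. With the pair itself among the fitted arrays the value was 0.47. The fit without the pair was chosen after seeing the data.

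Whether probes that differed in mature N61 embryos differed the same way earlier was asked over the 27374 probes tested in both. Their Spearman correlation over probes was 0.348 and their Pearson correlation 0.374. Of the 2919 mature calls among them, 77.5% had the same sign in the time course. Probes are not independent, so these values describe the arrays and no test was made. The 25 °C arrays of 29 and 34 days lay 0.27 and 0.28 from the mature 25 °C embryo. Part of the time course is thus close to maturity, and the shared sign does not rest on earlier stages alone. The Spearman value was 0.276 for the dye-swapped replicate alone and 0.11 with days in place of relative age. None of the 4 probes named over both cultivars passed the test of the time course difference. The fitted values were log2 3.48 for wheat0130Contig12202 (adjusted p = 0.054), 2.33 for wheat0130Contig787 (adjusted p = 0.12), -2.12 for wheat0130Contig6297 (adjusted p = 0.19) and 0.35 for MUGEST2003_23lib_Contig7628_m_1111 (adjusted p = 0.94), whose mature effect had the opposite sign. At 25 °C wheat0130Contig12202 went from log2 -1.19 at 15 days to -4.45 at 34 days relative to the mature 13 °C embryo, while at 13 °C it lay between 0.00 and 1.06. At 25 °C wheat0130Contig787 went from -0.19 at 15 days to -2.83 at 20 days and -3.39 at 34 days, and at 13 °C from 1.57 at 25 days to -0.98 at 53 days and -0.13 at 62 days. The probe of wheat0130Contig6297 stood at 2.07 to 3.26 at 25 °C and at 0.09 to 1.36 at 13 °C. The probe of MUGEST2003_23lib_Contig7628_m_1111 rose at both temperatures, from -1.33 at 25 days to 2.98 at 53 days and 1.91 at 62 days at 13 °C, and from -1.72 at 15 days to 3.61 at 34 days at 25 °C.

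**Figure D4:**
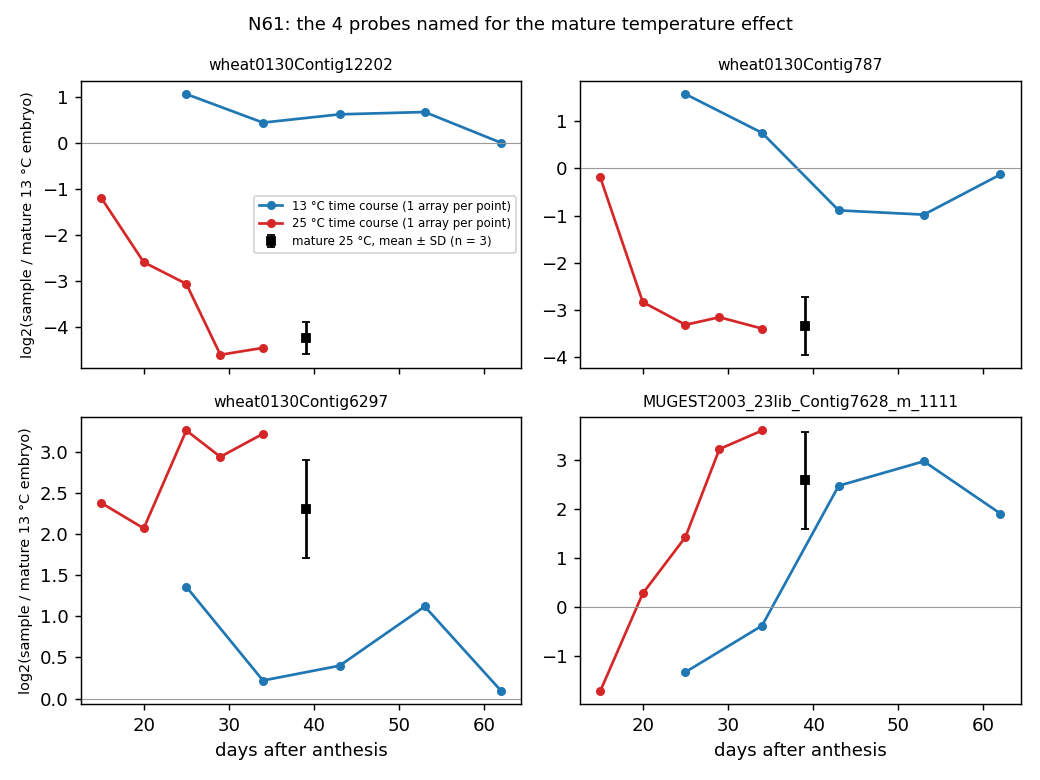
Log2 ratio to the mature 13 °C N61 embryo (y axis) against days after anthesis (x axis) for the 4 probes named over both cultivars, with 1 array per point in blue (13 °C) and red (25 °C) and the mature 25 °C embryo in black (mean ± SD, n = 3). At 25 °C wheat0130Contig12202 lies at -4.45 by 34 days, and at 13 °C it stays between 0.00 and 1.06.

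Of the 37826 probes, 6 carry a gene name in the files, namely RD29A, RD29B, cor47, Wcor15, DREB2A and DREB2B. In mature embryos RD29A, cor47, Wcor15, DREB2A and DREB2B were not well above background on any of the 8 arrays at either temperature and were not tested. RD29B, given outside the naming rule as the only tested probe with a gene name, was well above background on 5 of 8 arrays at each temperature and did not differ past the threshold, with a log2 value of -0.09 ± 0.07 (SE, n = 6, adjusted p = 0.38) over both cultivars. Its slopes were 0.05 ± 0.06 per 10 days at 13 °C and 0.11 ± 0.13 at 25 °C (adjusted p = 0.67 and 0.57). In the time course RD29B was well above background in the sample channel on 2 of 10 arrays and in the reference channel on 4. These slopes thus lie near background and do not show that its level was constant. With Feature Extraction's ratios its slope at 25 °C was 0.51 (limma, adjusted p = 0.091). Of the 22 gene lists fixed in advance, only that of cold-regulated genes had any members by name, 4 of which 0 could be tested, so no list was tested as a set.

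The reference channel (Cy3 alone, quantile normalized between arrays) gave a part of the technical spread of the time course. Its median SD per probe over the 10 arrays was 0.067 on the log2 scale, and the 95th percentile was 0.285. These values hold no spread of the Cy5 channel or of the samples' extraction. They are thus not the technical spread of the loess ratios that were fitted.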

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

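Of the tests in this part, those of the scan session, of faster development and of slides, and the turning of paired replicates together, were chosen after the results were seen.

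Among the 4 arrays of mature N61 embryos, the dye-swapped array stood apart in the share of probes well above background in Cy3, at 69.1% against 71.1% to 71.3% on the others. It is the array whose Cy3 channel held the 25 °C embryos. The dye-swapped array of SK was also the lowest of its 4, at 69.3% against 71.9%, 72.8% and 73.9%, without standing apart by the same measure. Chance marks about 1 in 20 groups in this way, and 10 groups of values were looked at. Both swapped arrays went the same way, and no explanation of this was tested.

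Replicate 1 of N61 resembled replicate 1 of SK (correlation 0.783 over probes) more than replicates 2 and 3 of its own cultivar (0.498 and 0.564). Dye bias cancels in replicate 1 and not in the others. The dye effect of the other cultivar's swap pair was taken out of replicates 2 and 3. The mean correlation of replicate 1 with its own cultivar's other replicates then went from 0.463 to 0.451. That effect had an SD of 0.107 (N61) and 0.110 (SK), against 0.367 to 0.435 for the ratios of replicates 2 and 3. A dye effect of the size seen in the swap pairs is thus argued against. The dye effect of replicates 2 and 3, scanned in another session, was not measured, so a dye effect of their own stays open. Correlations between cultivars were higher within a scan session than across sessions by 0.251 on average. The scan session cannot be told apart from a difference between the embryos of the repeats, since only replicate 1 was scanned in the first session, so both stay open.

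The time course gave 7281 probes that differed between temperatures when age was counted in days and 4 at relative age. A candidate explanation is that embryos passed through the same stages in fewer days at 25 °C. Distances between the arrays that gave these counts were compared, so this is no separate test. The day-matched distances of 1.06 and 1.26 each count for both of their arrays. The 4 arrays with a day-matched array at the other temperature lay 2.44 times as far from it as from the array nearest in relative age. The mean distances were 1.16 against 0.48, and the ratio was 2.61 without the pair of the shared slide. Likeness of arrays on a slide is argued against as the source of these short distances, since the shared slide's pair lay at 0.53 and the 25 °C array of 15 days lay nearer, at 0.42, to a 13 °C array on another slide. Beyond that pair, temperature and slide are confounded in the time course, and each time point rests on 1 array.

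Other splits of the samples were used to ask whether the counts could come by chance, at a share under 0.05. For N61, SK and both cultivars the 4 patterns of turned signs are too few for such a share, with 1 of 4 as large in each (2935, 3522 and 8178 against a highest other of 0). For both cultivars, same-numbered replicates were turned together because the numbers pair the samples. Turned independently, which the pairing does not allow for, 32 patterns gave a highest other of 2. For the cultivar difference all 10 of 10 splits gave 0 probes (limma, 829 at an unadjusted p under 0.05 in the real split), and 10 splits are too few. For the trends the real order of time points gave the most probes among 60 orders, 1 of 60 at each temperature, with 4241 against 3181 at 13 °C and 6850 against 6098 at 25 °C, so a random order can be excluded. For the temperature difference of the time course 4 of 100 splits gave at least its 4 probes, the real one included, a share under 0.05. That count rests on leaving out the 5 spots of high background after seeing the data, since with them kept 0 probes passed (limma, 2180 at an unadjusted p under 0.05), so chance is not excluded for it. The highest other split gave 1019 probes. It set the 13 °C arrays of 25, 43 and 53 days and the 25 °C arrays of 25 and 34 days apart from the rest. That split follows no slide, and its cause was not tested. Change with age that relative age and its square do not follow stays open. A list of 4 probes is small beside 1019.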

How the results depend on the processing

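Keeping spots of high background, the later session alone, the slide as a fixed block, the replicate block for the mature effects, the inclusion of RD29B in the settings, the setting of the reference channel, and 2 settings of the comparison with the time course were chosen after seeing the data. For N61, SK and both cultivars the counts stayed within 1.5 times with Feature Extraction's ratios, the series table, no background correction, no filter, the strict filter, the dye term and the swapped arrays left out. Aquantile scaling moves no ratio and gave equal counts. Median centring gave 1541 for N61, and moved the share of higher calls from 47.6% to 15.4% in N61, from 41.8% to 12.8% in SK, from 47.7% to 20.9% over both and from 39.9% to 24.6% for the trend at 13 °C. The trended and robust spread gave 1336 (N61) and 1893 (SK), and SK alone gave 7. The slide as a random block gave 1422, 1466 and 3699 for N61, SK and both, and the scan session as a block 8510, 9367 and 13621. The replicate block, which takes the difference between sessions out of the spread, gave 8021, 8709 and 13203, left the cultivar difference at 0 and kept each probe given by name on its side of the threshold. A 2-fold threshold gave 435, 495 and 478. The later session alone gave 4427 (N61) and 6173 (SK). Without each replicate in turn the counts ranged from 37 to 4511 (N61), 451 to 3329 (SK) and 4713 to 8333 (both). The cultivar difference stayed at 0 probes in every setting tried, with 429 to 2142 at an unadjusted p under 0.05.

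Both trend counts stayed within 1.5 times under every setting except time points left out, with 0 to 3426 at 13 °C and 0 to 6602 at 25 °C. Relative age only rescales a slope within a temperature. The temperature difference of the time course gave 1 with Feature Extraction's ratios, 7281 with days, 0 with the serial number, 0 with the slide as a random block, 51 with it fixed and 0 with spots of high background kept, and 0 to 15 without each time point. The comparison of mature and time course effects gave 0.276 with the swap pair alone and 0.11 with days. Settings with a replicate, time point or cultivar left out hold fewer samples, and the cause was not tested for the others. Over all settings and probes given by name, sign and side of the threshold were the same in 509 cases and the call was lost in 64. The 509 include settings that could not change a call, so they overstate the stability. Such settings were Aquantile scaling, relative age within a temperature, the 2-fold threshold and, for mature embryos, spots of high background kept. The series table repeated Feature Extraction's ratios. In 11 cases the sign changed, all of RD29B, which passed in no setting. Its N61 effect was 0 with Feature Extraction's ratios and the series table. Its cultivar difference was -0.07 with median centring, -0.03 with no background correction, -0.10 without N61 replicate 1, -0.04 without SK replicate 3 and -0.07 in the later session, and ranged from -0.10 to 0.08 without each replicate. Its slope at 13 °C was -0.02 with median centring and 0 with no background correction, and its time course difference 0 with median centring and 0.01 without the 25 °C array of 15 days, with a range from -0.11 to 0.01 without each time point. The spread of the reference channel was 0.064 with no background correction. Gene list settings were not run because no list could be tested. Probes not well above background, beyond the 63.6% to 78.9% per array that were so in Cy5, are limited by it.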

Other observations

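The test of age and the look at probe pairs were chosen only after the results were seen, and some of the correlations with the slopes were known when the bound of the age test was written.

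At 25 °C the arrays of 29 and 34 days differed by 0.21 (SD over probes), with 52 probes at least 2-fold apart, and both lay within 0.28 of the mature 25 °C embryo of 39 days. At 13 °C the arrays of 53 and 62 days lay 0.87 apart. On the array of 62 days the SD of its ratio to the mature 13 °C embryo was 0.25, a value within an array and not a distance between arrays. Across temperatures the 62-day array lay 0.40, 0.49 and 0.50 from the 25 °C arrays of 29, 34 and 39 days, and 1342 probes were at least 2-fold apart in the last pair. The arrays of 29 and 34 days at 25 °C share a slide, as do those of 53 and 62 days at 13 °C, and the time points have no replicates.

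A hypothesis is that the mature difference between temperatures may reflect embryos of different developmental age. If it did, the mature N61 effect would follow an age axis of the time course. The Spearman correlations of the mean of N61 replicates 2 and 3 with the slope at 13 °C, the slope at 25 °C, the step from 53 to 62 days at 13 °C and the step from 29 to 34 days at 25 °C were 0.056, -0.041, 0.109 and 0.162. The largest was 0.162, so the effect in replicates 2 and 3 followed none of these axes closely. This does not decide about age. The step from 29 to 34 days was small (0.21, 52 probes at least 2-fold apart), which leaves little to correlate with. No axis held the last step to the mature embryo at either temperature, where a difference in age could lie. Replicate 1 was not part of this test. Age stays open, and so does a lasting effect of temperature, which was not tested. Of the N61 mature calls also tested in the time course, 77.5% had the same sign there at the same relative age (Spearman value over all probes 0.348). With days in place of relative age the Spearman value was 0.11. The late arrays lie close to the mature embryos, and temperature is largely confounded with slide, so the shared sign does not decide between these explanations.

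For 833 contigs the array holds 2 probes whose names differ in a p or m. Both were well above background on all mature arrays for 53 contigs, and only 1 of them for 408. Among the 53 the temperature effects over both cultivars correlated at a Spearman value of 0.14 and had the same sign in 47.2%. What the letters stand for is not given in the sources used here.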
